A study of Mus musculus with 6 samples.

How the data were processed

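The data were 6 libraries from mouse embryonic stem cells, 3 from an EGFP control line and 3 from a line carrying EWS-OCT4A fused to GFP, all given doxycycline at 1 µg/ml to lower endogenous OCT-4. Per the labels' protocols, RNA was taken up in Trizol and 500 ng of total RNA went into a Lexogen QuantSeq kit, which reads transcript 3′ ends. The submitters' processing notes list Bowtie2, edgeR and the build mm10, without versions or the step that each served. Samples were grouped by their titles. The design states that experiments were done in triplicate but not whether the 3 libraries of a line came from separate cultures. P-values of the gene tests therefore measure only the spread between these samples. List tests also compare genes with other genes. Fisher's exact test and random gene sets, used in the closing section, measure spread across genes and not between libraries.

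The deposited values were whole-number counts per gene symbol, 1 file per library. No scaling was found in them: totals differed between libraries and the low whole numbers were all in use. The counting tool, the annotation and the use of strand are not given in the sources used here. Each file held 23282 lines and 23238 symbols. The 35 symbols that appeared more than once (79 lines) were summed, and 4305 symbols had no count in any library. No mitochondrially encoded symbol was in the files.

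Depth ran from 10978025 to 14935887 counts per library, so that 1 count stood for 0.0670 to 0.0911 CPM. Where a line had no count, its level was set to a floor of 3 counts per library and the change is given as at least that fold. Where a line had 1 to 3 counts in all, the depth-scaled ratio is given with its exact 95% interval. Floors and intervals cover counting error only.

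Counts were scaled by TMM in edgeR 4.0.16 (factors 0.971 to 1.03), filtered with filterByExpr (minimum count 10, minimum total 15), and tested by a robust quasi-likelihood F test of line against line, 2-sided, with Benjamini-Hochberg adjustment at 0.05. Of all symbols, 13467 were tested and 9771 were not. The biological coefficient of variation was 19.3%. The SE of a log2 fold change was its size divided by the square root of F. Gene lists were tested with camera (limma 3.58.1) on log CPM with a prior count of 2, at the preset correlation of 0.01 between genes, adjusted over the 25 lists with at least 3 tested members. The value given for a list is the median log2 fold change of its tested members. Counts of list members are of tested members too, and some lists lost many members to the filter. Tested were 16 of 33 FGF ligands, receptors and adaptors, 5 of 15 primitive streak and 14 of 23 primitive endoderm genes. For neural ectoderm and Ewing sarcoma it was 9 of 16 each, and for mesenchyme 14 of 21.

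Fixed before the data were examined were the tests, the threshold, the members of all 26 lists and the rule for named genes. The lists covered the pluripotency network, formative and primed epiblast, trophoblast, primitive endoderm, primitive streak and mesoderm, neural ectoderm, FGF ligands, receptors and adaptors, FGF-ERK feedback and target genes, cell cycle progression, cell cycle inhibitors, p53 targets and apoptosis, the integrated stress response, Nodal and BMP readouts, WNT targets, the LIF-STAT3 axis, epithelial junctions, mesenchyme and fibroblasts, glycolysis, cholesterol biosynthesis, interferon response, the 2-cell-like state, germline genes, genes activated in Ewing sarcoma, imprinted genes, Y-linked genes and mitochondrially encoded genes. The rule named Pou5f1 and Ewsr1. It named the 8 largest rises and the 8 largest falls among called genes whose libraries did not overlap between lines and whose mean was at least 10 CPM. It named the called members with the largest change, up to 5 for the FGF, FGF-ERK, pluripotency, trophoblast and cell cycle progression lists and up to 3 for the others. It also named all called Fgf and Fgfr genes. Other genes are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

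The gene test was tested on simulated data for 13398 genes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 77% and 99% of them, with 6.88% false calls, above the nominal share, and 0 calls of the wrong sign. Of 200 simulated lists without a change, 1% had p under 0.05. These lists do not test the preset correlation between genes in camera, so they cannot decide between it and an estimated correlation. The simulation changed few genes, whereas 67.4% of tested genes passed in the data. Recovery, false calls and TMM scaling were not tested with so large a share of changed genes.

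Alternatives set beforehand were leaving out each library, a block on replicate number, DESeq2 size factors in edgeR, no filter, a mean of at least 10 CPM, limma-voom, DESeq2 1.42.0, a test against a 1.5-fold change, an adjusted p of 0.01, an estimated correlation in camera, and the rotation test fry. Added after seeing the data were a fit without Rn45s, a fit of the libraries numbered 1 and 2 only, and a term for the libraries numbered 3. Locations and transcript GC came from GENCODE M21 on GRCm38, which is the assembly of mm10. Gene families in the closing section were compared with all other tested genes by Fisher's exact test, 2-sided. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.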

Results

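The data comprised 6 libraries of 3′ RNA tags from mouse embryonic stem cells of strain 129/Ola. Both lines were stable lines of cells that the labels name Niwa. The control line carried EGFP and the experimental line carried EWS-OCT4A fused to GFP, a fusion of the Ewing sarcoma protein EWS with isoform A of OCT-4. Each line gave 3 libraries. Both lines were kept in stem cell medium with LIF and given doxycycline at 1 µg/ml to lower endogenous OCT-4. The design compares the lines with each other, so it asks how expression in cells that carry the fusion differed from that in control cells when endogenous OCT-4 was low. No library was without doxycycline, so rose and fell here mean higher and lower in the EWS-OCT4 line than in the EGFP line. Which line moved from its state before doxycycline cannot be told. Effects of the fusion also cannot be told apart from other differences between the lines. The 3 EGFP libraries held 13239383, 14091315 and 14935887 counts, and the 3 EWS-OCT4 libraries held 10978025, 11010932 and 12281444. The ribosomal RNA precursor Rn45s took 6.44%, 6.10% and 5.85% of the counts in the EGFP libraries and 10.4%, 10.5% and 7.36% in the EWS-OCT4 libraries (Wilson 95% interval of the first 6.43 to 6.45, the others as narrow). Levels are in TMM-scaled CPM, as mean ± SD with n = 3 per line, and fold changes compare the EWS-OCT4 line with the EGFP control line on the log2 scale, with their standard error (SE). No label says that the 3 libraries of a line came from separate cultures, so p-values of the gene tests measure the spread between these samples, which may be technical.

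The genes of the fusion were examined first. Pou5f1, which encodes OCT-4, was near the detection floor in both lines, with 5, 13 and 10 counts in the EGFP libraries and 18, 21 and 36 counts in the EWS-OCT4 libraries. Its level was 0.644 ± 0.269 CPM in the EGFP line and 2.21 ± 0.719 CPM in the EWS-OCT4 line, a difference of 1.76 on the log2 scale (SE 0.51, adjusted p = 0.0108 by edgeR's quasi-likelihood test). Without EWS-OCT4 replicate 3 the adjusted p of Pou5f1 was 0.0542, and over the 6 libraries left out in turn it lay between 0.0177 and 0.0542. Ewsr1, the mouse gene for EWS, stood at 100.3 ± 8.44 CPM and 83.6 ± 25.7 CPM (log2 difference -0.26, SE 0.21, adjusted p = 0.295) and did not pass the test. Its sign depended on the libraries numbered 3, since the log2 difference was 0.06 in the libraries numbered 1 and 2 alone. The 3′ end of the fusion transcript is not given in the labels, so whether tags counted at either gene come from the fusion is not known, and they cannot check the labels. In GENCODE M21 (GRCm38, the same assembly as mm10) Pou5f1 lies on chromosome 17 at 35506018 to 35510772 on the plus strand, overlapped on the opposite strand by Gm19553, and Ewsr1 lies on chromosome 11 at 5069689 to 5099266 on the minus strand.

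Expression differed between the lines in most of the genes measured. Of 13467 genes tested, 9073 (67.4%) passed an adjusted p of 0.05, with 4482 higher and 4591 lower in the EWS-OCT4 line. A change of at least 2-fold was found in 6112 of these genes, 2933 higher and 3179 lower, and a change of at least 8-fold in 798 higher and 964 lower genes. The 3 values of one line lay wholly above those of the other for 72.7% of the tested genes, where chance gives 10%. The first principal component held 90.4% of the variance and separated the lines. The libraries numbered 3 stood apart from numbers 1 and 2 of their own line, with a chi-square per degree of freedom of 25.3 and 26.8 in the EGFP line and 34.4 and 34.6 in the EWS-OCT4 line, against 4.01 and 4.31 between numbers 1 and 2. Using only the libraries numbered 1 and 2, 10240 genes passed, and 8840 of the 9073 were among them.

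The 8 largest falls were in genes of several kinds, of which Plac1 is in the trophoblast list. Plac1, a placental gene on chromosome X (53069995 to 53240111), was at 90.3 ± 5.40 CPM in the EGFP line and had no count in the EWS-OCT4 line. With a floor of 3 counts per library, its level was at least 336-fold lower. Olr1, a receptor for oxidised lipoprotein, was at least 685-fold lower, Serpinb9g, a serpin of a cluster of near-identical genes, at least 253-fold lower, and Cdh5, the cadherin of endothelial cells, at least 190-fold lower. Cd82, BC051665 and BC053393 also had no count in the EWS-OCT4 line, and were at least 154-fold, 151-fold and 151-fold lower. Chrdl2, a secreted BMP antagonist, had 5240 counts in the EGFP line and 1 in the EWS-OCT4 line, a depth-scaled ratio of 4088 (exact 95% interval 733 to 161491). Without EWS-OCT4 replicate 2, which held that count, it was at least 462-fold lower, and without EWS-OCT4 replicate 3 the ratio was 2638 (interval 473 to 104213).

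The 8 largest rises included members of the Nodal and BMP, pluripotency and neural ectoderm lists. Lefty2, a secreted Nodal inhibitor on chromosome 1 (180893108 to 180899103), had 2 counts in the EGFP line and 8852 in the EWS-OCT4 line, a ratio of 5673 (exact 95% interval 1570.1 to 46855). Nr0b1, a nuclear receptor of the pluripotency network, had 1 count against 4893 (ratio 6272, interval 1125 to 247785). Sox1, a transcription factor of early neural cells, had 1 count against 1655 (ratio 2121, interval 380.2 to 83844). Vegfc, a growth factor for lymphatic vessels, and Trh, the thyrotropin-releasing hormone gene, had no count in the EGFP line and were at least 215-fold and 96.0-fold higher. Fam25c had 3 counts against 3979 (ratio 1700.2, interval 581 to 8248) and Gm38437 had 3 against 2049 (ratio 876, interval 299 to 4249). The small nucleolar RNA Snora19 had 2 counts against 3854 (ratio 2470.1, interval 683 to 20404). It lies inside Eif3a on the same strand (chromosome 19, 60774330 to 60774461), so its tags are uncertain, although Eif3a itself, named after its values were seen, went from 1499 ± 105 to 1954 ± 190.4 CPM. The EGFP counts of Lefty2, Nr0b1, Sox1, Snora19 and Gm38437 were all in EGFP replicate 3, 1 of the libraries that stand apart. Without that library they had no count in the EGFP line and were at least 1208-fold, 680-fold, 229-fold, 527-fold and 280-fold higher. Without EGFP replicate 1, Fam25c had 1 count in that line and a ratio of 3512 (interval 630 to 138733). These intervals and floors cover counting error only.

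The pluripotency network was higher in the EWS-OCT4 line. Of its 32 genes, 30 rose, none fell and 2 did not pass the test, over all genes and adjusted over the list alone, with a median of 2.59 on the log2 scale. Sox2, a partner of OCT-4 on DNA (chromosome 3, 34650405 to 34652461), rose from 7.02 ± 4.84 to 1333 ± 29.95 CPM (log2 difference 7.55, SE 0.41, adjusted p = 2.1e-07). Esrrb, an orphan receptor of naive stem cells, rose from 1.38 ± 0.358 to 418 ± 15.3 CPM (8.22, SE 0.19, adjusted p = 3.8e-09). Tdgf1, a Nodal co-receptor, rose from 2.12 ± 0.304 to 538 ± 33.9 CPM, and the TGF-β family ligand Gdf3 from 0.185 ± 0.0319 to 49.3 ± 3.01 CPM. Nanog, chosen after its values were seen, rose from 23.4 ± 13.1 to 547 ± 117 CPM. The 2 that did not pass, named after their values were seen, were Fbxo15 (0.09) and Trim71 (-0.10). The list test (camera) gave adjusted p = 5.0e-12 at its preset correlation and adjusted p = 0.227 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 2.7e-23. EGFP replicate 3 lay above EGFP replicates 1 and 2 over this list, by a median of 0.42 on the log2 scale, and without it the difference in Sox2 was 8.29.

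**Figure D1:**
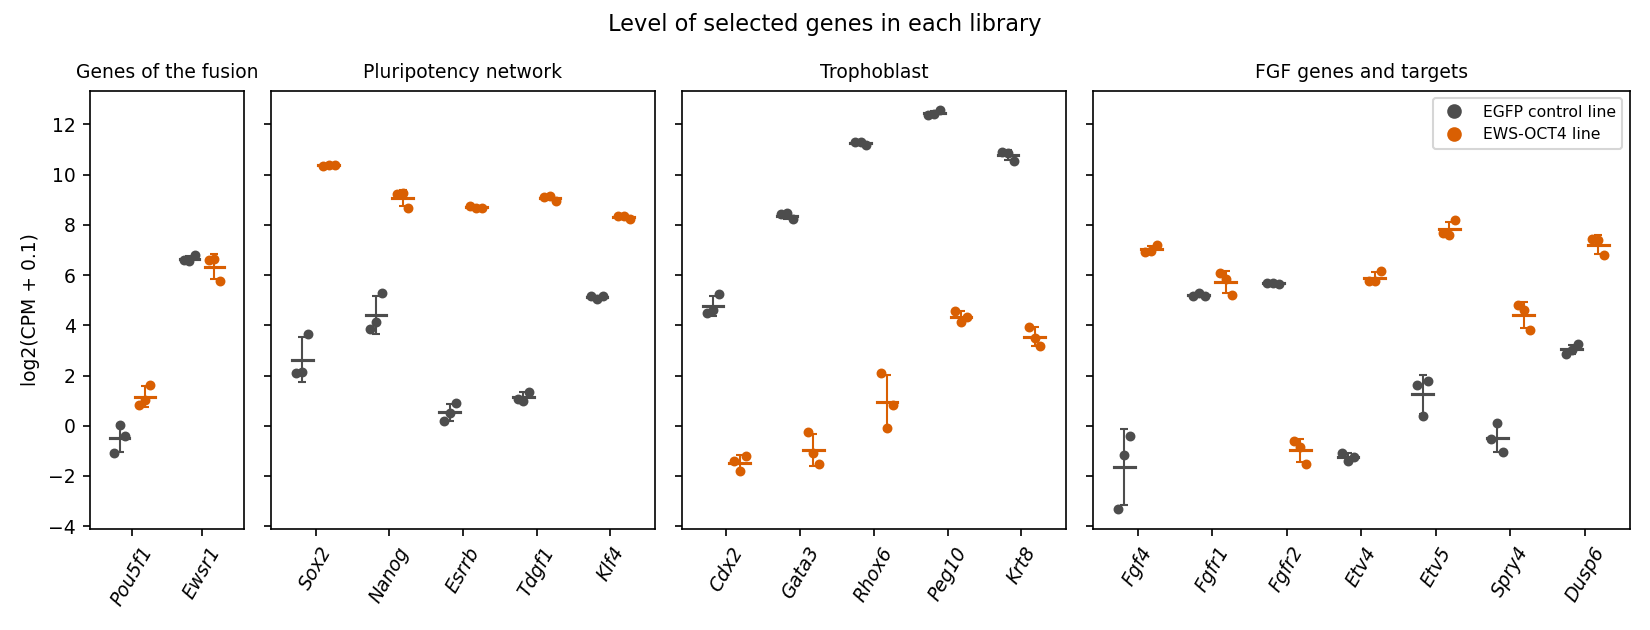
Level of selected genes in each library, as log2(CPM + 0.1) on the vertical axis, for the genes of the fusion, the pluripotency network, trophoblast genes and FGF genes with their targets. Points are the 3 libraries of the EGFP control line (grey) and of the EWS-OCT4 line (orange), and bars give the mean and SD of the plotted values. Sox2 rose from a mean of 7.02 to 1333 CPM while Rhox6 fell from 2472 to 2.22 CPM, and the values of the lines did not overlap for these genes, but did for Ewsr1 and Fgfr1.

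Trophoblast genes, which mark the lineage that forms the placenta, were lower in the EWS-OCT4 line. All 29 tested members fell, over all genes and adjusted over the list alone, with a median of -7.34 on the log2 scale, or -7.12 with the 3 members that had no count in the EWS-OCT4 line set at their bound. The homeobox genes Rhox6 (chromosome X, 37826910 to 37829857) and Rhox9 fell from 2472 ± 121 to 2.22 ± 1.72 CPM (log2 difference -10.12, SE 0.39, adjusted p = 3.6e-08) and from 1397 ± 81.9 to 1.54 ± 0.646 CPM. They belong to a cluster of related genes whose reads can be shared. Gata3, a transcription factor of trophoblast, fell from 332 ± 26.7 to 0.453 ± 0.253 CPM (-9.51, SE 0.25). Prl3d1, a placental lactogen, was at 29.4 ± 21.5 CPM in the EGFP line, with 534, 625 and 73 counts, and at 0 in the EWS-OCT4 line, at least 110-fold lower. Of members chosen after their values were seen, Cdx2 fell from 28.0 ± 8.18 to 0.265 ± 0.0761 CPM, and the keratins Krt8 and Krt18 from 1755 ± 231 to 11.9 ± 3.16 CPM and from 1617 ± 74.7 to 6.31 ± 2.73 CPM. The list test gave adjusted p = 6.3e-14, and adjusted p = 0.153 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 4.6e-40. EGFP replicate 3 lay below EGFP replicates 1 and 2 over this list, with a median of -0.20 on the log2 scale, and EWS-OCT4 replicate 3 lay below numbers 1 and 2 of its line by a similar median (-0.19). The difference in Rhox6 was -10.91 without EWS-OCT4 replicate 1.

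Imprinted genes and epithelial junction genes were lower in the same comparison. Of 19 imprinted genes, 17 fell and 2 rose (median -3.88 on the log2 scale). The growth factor gene Igf2 fell from 3278 ± 407 to 3.64 ± 3.89 CPM, the neighbouring non-coding RNA H19 from 1808 ± 55.3 to 2.65 ± 1.86 CPM, and Peg10, a retrotransposon-derived gene needed for the placenta that is also in the trophoblast list, from 5641 ± 349.8 to 20.5 ± 3.22 CPM. Mest and Igf2r, named after their values were seen, rose by 1.35 and 1.07 on the log2 scale. Of 19 epithelial junction genes, 18 fell (median -2.47). The splicing factor Esrp1 fell from 119.6 ± 20.2 to 1.24 ± 0.164 CPM, and the desmosomal genes Dsc2 and Dsp from 62.6 ± 19.05 to 0.841 ± 0.813 CPM and from 221 ± 69.9 to 8.95 ± 2.11 CPM. List tests gave adjusted p = 5.6e-05 for imprinted genes and 5.2e-06 for junction genes. Each had adjusted p = 0.153 with an estimated correlation, the highest of 16 alternatives of this test, with lowest values of 3.0e-11 and 3.4e-09. Leaving out EWS-OCT4 replicate 1 moved Igf2 from -9.83 to -11.12, H19 from -9.42 to -10.15 and Dsc2 from -6.21 to -7.27, and the imprinted median was -3.18 in the libraries numbered 1 and 2 alone. Over imprinted genes both libraries numbered 3 lay below numbers 1 and 2 of their line, with medians of -0.32 (EGFP) and -0.24 (EWS-OCT4).

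FGF signalling is named in the title of the study, and its ligands and receptors changed in both directions. Of 16 tested ligands, receptors and adaptors, 9 rose, 5 fell and 2 did not pass the test, over all genes and adjusted over the list alone. Fgf4, the main FGF ligand of stem cells (chromosome 7, 144847367 to 144865243), rose from 0.333 ± 0.325 to 130.9 ± 14.02 CPM (log2 difference 8.52, SE 0.40, adjusted p = 8.8e-08). Its neighbour Fgf15 had no count in the EGFP line and 140 in the EWS-OCT4 line, at least 20.1-fold higher. Lower levels rose for Fgf1 (1.55 ± 0.924 to 8.69 ± 2.55 CPM) and Fgf11 (0.208 ± 0.0666 to 1.21 ± 0.335 CPM), while Fgf9 had 73 counts against 3, a ratio of 18.98 (exact 95% interval 6.24 to 94.2). The receptor Fgfr2 fell from 51.1 ± 0.681 to 0.422 ± 0.154 CPM (-6.90, SE 0.25, adjusted p = 2.4e-08), and Fgfbp1, a secreted FGF-binding protein, from 39.1 ± 1.96 to 0.716 ± 0.766 CPM. Fgfr3 rose from 2.18 ± 0.561 to 7.39 ± 1.41 CPM and Fgfr4 from 0.941 ± 0.438 to 3.77 ± 0.709 CPM. Fgfr1 was at 37.2 ± 1.68 and 54.5 ± 15.8 CPM (0.55, SE 0.21, adjusted p = 0.0362), and this call was lost in 5 of the 6 fits that left out 1 library (without EGFP replicate 1, 2 or 3 or EWS-OCT4 replicate 1 or 2), where the adjusted p reached 0.161, and with limma-voom (0.0519). The annotation gives Fgfr2 a span on chromosome 7 of 130162451 to 133123350 that covers many other genes. Single libraries moved some of these differences: Fgf4 was 9.42 without EGFP replicate 3, Fgfbp1 went from -5.71 to -7.09 without EWS-OCT4 replicate 3, and the ratio of Fgf9 was 11.3 without EGFP replicate 2 (exact 95% interval 3.50 to 57.8) and 36.8 without EWS-OCT4 replicate 3 (6.39 to 1471).

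As a set, these FGF genes showed no net shift in 1 direction against other genes by the list test (adjusted p = 0.627, and 0.701 with an estimated correlation). That test does not show that they were unchanged, since 9 rose and 5 fell. The median was 1.09 and the mean 0.51 on the log2 scale. The median was -2.44 when only genes with a mean of at least 10 CPM were tested, which left 6 members, 4 of them lower, with adjusted p = 0.187, the lowest of 16 alternatives of this test, of which the highest was 0.884. The rotation test fry, which asks whether the genes moved on balance one way, gave adjusted p = 0.487.

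Genes that FGF-ERK signalling is known to induce were mostly higher. Of 20 tested feedback and target genes, 13 rose, 4 fell and 3 did not pass the test, over all genes and adjusted over the list alone (median 1.55 on the log2 scale). The ETS factors Etv4, Etv1 and Etv5 rose from 0.326 ± 0.0461 to 59.9 ± 9.34 CPM (7.48, SE 0.25, adjusted p = 2.2e-08), from 0.0930 ± 0.0811 to 18.003 ± 2.30 CPM and from 2.49 ± 1.14 to 230 ± 52.2 CPM. The feedback inhibitor Spry4 rose from 0.656 ± 0.30 to 22.2 ± 7.23 CPM, and Dusp6, an ERK phosphatase chosen after its values were seen, from 8.19 ± 1.08 to 152 ± 35.9 CPM. The 4 genes that fell were Myc and, named after their values were seen, Fosl1, Fos and Phlda1. Myc, a growth regulator with many other inputs, fell from 19.9 ± 5.82 to 0.732 ± 0.523 CPM (-4.77, SE 0.47). The list test gave adjusted p = 0.0055, and adjusted p = 0.153 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 7.7e-05. The median was 2.66 when only genes with a mean of at least 10 CPM were tested.

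**Figure D2:**
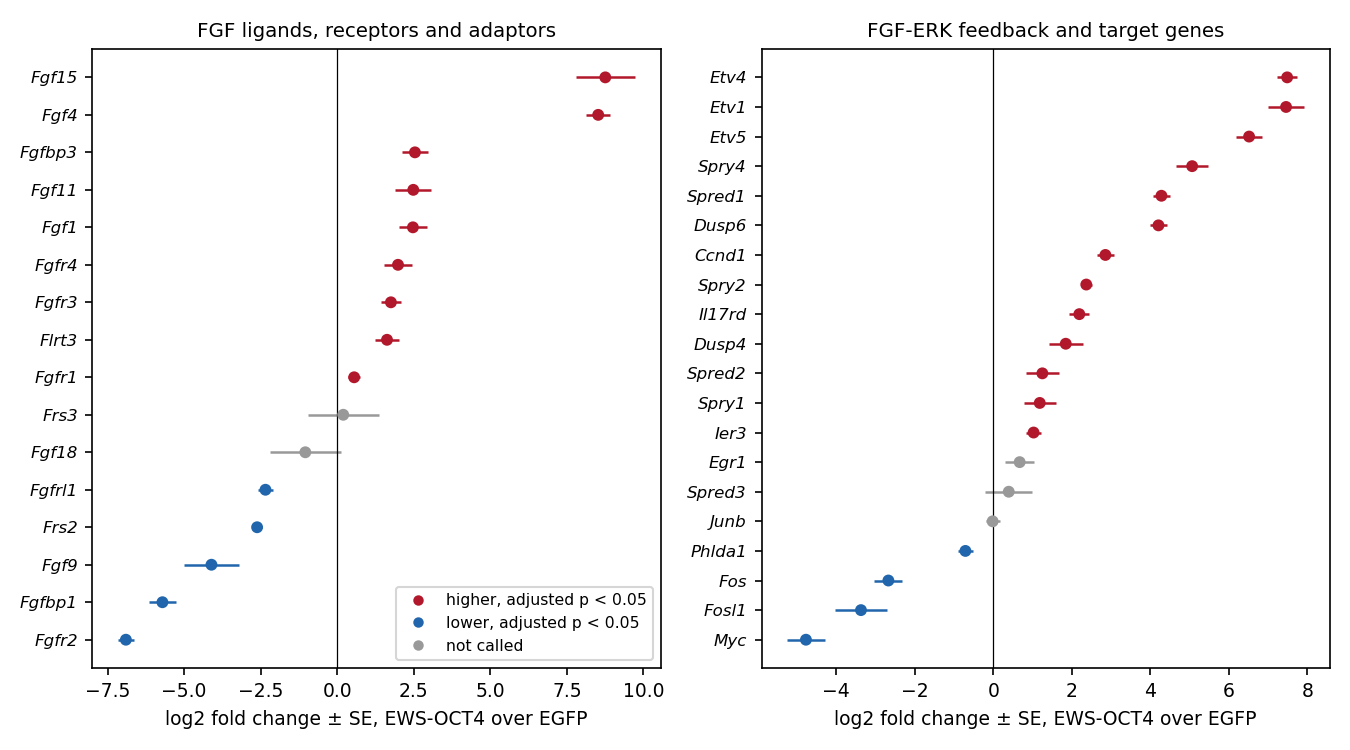
Log2 fold change of the EWS-OCT4 line over the EGFP control line (horizontal axes) for the 16 tested FGF ligands, receptors and adaptors and the 20 tested FGF-ERK feedback and target genes. Points are edgeR estimates from 3 libraries per line, bars give the SE, and colour gives the call at an adjusted p of 0.05. Fgf4 lay at 8.52 and Fgfr2 at -6.90, and the estimate for Fgf15, which had no count in the EGFP line, depends on the fitted prior count.

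The title also names proliferation. Of 30 genes of cell cycle progression, 22 rose, 1 fell and 7 did not pass the test (23 rose and 1 fell adjusted over the list alone), with a median of 1.12 on the log2 scale. The replication licensing genes Mcm3, Mcm7 and Mcm6 rose from 116 ± 17.1 to 679 ± 23.4 CPM (2.55, SE 0.13, adjusted p = 1.8e-07), from 189 ± 25.1 to 883 ± 100.5 CPM and from 69.2 ± 21.8 to 289 ± 45.5 CPM. E2f1, a transcription factor of S phase entry, rose from 17.1 ± 3.14 to 74.8 ± 12.7 CPM and the kinetochore gene Cenpf from 178 ± 81.9 to 544 ± 103 CPM. Ccne2, named after its values were seen, was the member that fell (-0.86). The list test gave adjusted p = 9.2e-06, and adjusted p = 0.362 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 6.3e-09. The median differed between the libraries, at 1.36 for numbers 1 and 2 and 0.63 for number 3, and EGFP replicate 3 lay above EGFP replicates 1 and 2 by a median of 0.41.

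Cell cycle inhibitors moved apart. Of 12 tested, 3 rose and 4 fell (median -0.05, adjusted p = 0.627). Cdkn2a, which encodes p16 and p19ARF, rose from 5.32 ± 1.91 to 128 ± 25.1 CPM, Cdkn1c, an imprinted inhibitor, fell from 807 ± 126 to 21.0 ± 4.38 CPM, and Rb1 fell from 41.1 ± 6.13 to 6.04 ± 1.87 CPM. Of 19 p53 targets and apoptosis genes, 9 rose and 7 fell (10 and 7 adjusted over the list alone), with a median of 0.42 and adjusted p = 0.696. Among them Bcl2l1, an inhibitor of apoptosis, fell from 151 ± 19.3 to 30.5 ± 8.71 CPM, and Sesn1, a stress-induced regulator of growth, fell from 30.1 ± 9.66 to 7.02 ± 1.59 CPM.

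Markers of embryonic lineages other than trophoblast did not move as 1 group. Neural ectoderm genes were higher, with 7 of 9 tested members higher and 1 lower (median 2.14, adjusted p = 0.0108, and adjusted p = 0.153 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 0.0059). Besides Sox1, the homeobox gene Gbx2 rose from 0.677 ± 0.272 to 22.5 ± 4.94 CPM and Stmn2 from 0.308 ± 0.367 to 5.03 ± 0.152 CPM. Primitive endoderm genes were lower, with 10 of 14 lower and 3 higher (median -2.18, adjusted p = 0.0195, and adjusted p = 0.153 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 0.0023). That call was also lost without EGFP replicate 1 (adjusted p = 0.0552), EGFP replicate 2 (0.0686) or EWS-OCT4 replicate 3 (0.141). Gata6 fell from 31.2 ± 5.33 to 1.07 ± 0.653 CPM, Dab2 from 79.4 ± 6.19 to 1.53 ± 0.672 CPM, and Pdgfra had 120 counts against 1, a ratio of 93.6 (exact 95% interval 16.5 to 3728). Formative and primed epiblast genes split, with 6 of 12 higher and 5 lower (median 1.08, adjusted p = 0.372). That median was 2.33 when only genes with a mean of at least 10 CPM were tested (adjusted p = 0.219) and 2.27 without a filter on low counts (0.205). Over 16 alternatives of this test the adjusted p lay between 0.143 and 0.654. Foxd3 rose from 0.0898 ± 0.0983 to 22.2 ± 8.58 CPM, and Zic2 had 3 counts against 771, a ratio of 329 (exact 95% interval 112 to 1601). Only 5 of 15 primitive streak and mesoderm genes could be tested. Of these, Mesp2 rose, Kdr and Snai1 fell and 2 did not pass the test (median -1.22, adjusted p = 0.627). The median was -0.32 without EGFP replicate 2 and -2.19 without EWS-OCT4 replicate 3. Some sizes here rest on 1 library. Without EGFP replicate 3, Sox1 had no count in the EGFP line and was at least 229-fold higher, Stmn2 had a ratio of 46.4 (exact 95% interval 15.6 to 227) and Foxd3 a ratio of 609 (109 to 24081). Without EGFP replicate 2, Zic2 was at least 110-fold higher, and without EWS-OCT4 replicate 1, Pdgfra was at least 10.8-fold lower, since neither had a count left in its lower line. The ratio of Zic2 was 212 without EGFP replicate 3 (72.2 to 1029), and that of Pdgfra was 60.4 without EWS-OCT4 replicate 3 (10.6 to 2406). Without EWS-OCT4 replicate 2, Kdr went from -2.83 to -3.62 on the log2 scale. The neural median was 1.54 without a filter on low counts, or 1.42 with the 2 members that had no count in 1 line at their bound.

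Lists for other states and cell types gave no call. Of 13 germline genes, 2 rose and 3 fell (median -0.43, adjusted p = 0.696). The meiotic gene Stra8 rose from 2.55 ± 3.24 to 22.9 ± 5.07 CPM and Dazl rose from 1.45 ± 0.841 to 6.59 ± 1.35 CPM, while Sycp1 fell from 5.72 ± 1.90 to 0.905 ± 0.529 CPM. Of 6 tested genes of the 2-cell-like state, Zscan4a rose and Zfp352 fell (median -0.08, adjusted p = 0.945), and Zscan4a has near-identical copies. EGFP replicate 3 set much of the size of some low genes, since without it the log2 difference went from 3.14 to 5.02 for Stra8, from 2.02 to 3.32 for Zscan4a, from -2.48 to -1.86 for Zfp352 and from 4.40 to 5.05 for Prkcb. The 2-cell-like median ranged from -1.21 without EWS-OCT4 replicate 1 to 0.82 without EGFP replicate 3. The call on Zscan4a was lost without EGFP replicate 1 (adjusted p = 0.0648), EGFP replicate 2 (0.0807) or EWS-OCT4 replicate 2 (0.0705). Of 9 tested genes that are activated in Ewing sarcoma, 5 rose and 2 fell (median 1.27, mean 0.31, adjusted p = 0.372). The median was 0.59 without a filter on low counts (adjusted p = 0.596), and with only genes of at least 10 CPM on average it was 1.34 and passed (adjusted p = 0.0380, the lowest of 16 alternatives of this test, of which the highest was 0.623). Prkcb rose from 1.14 ± 0.876 to 24.5 ± 7.76 CPM, Steap1 rose from 9.02 ± 2.32 to 28.7 ± 4.28 CPM, and Sox6 had 116 counts against 1, a ratio of 90.5 (exact 95% interval 15.9 to 3605). Of 14 mesenchyme and fibroblast markers, which would show feeder cells, 4 rose, 3 fell and 7 did not pass the test (median 0.57, mean -0.14, adjusted p = 0.595). The median was 2.02 when only genes with a mean of at least 10 CPM were tested (adjusted p = 0.187, the lowest of 16 alternatives of this test, of which the highest was 0.701). Postn had no count in the EWS-OCT4 line and was at least 34.1-fold lower, Acta2 fell from 16.2 ± 6.54 to 0.762 ± 1.02 CPM and Thy1 rose from 0.636 ± 0.489 to 17.9 ± 1.45 CPM. EWS-OCT4 replicate 1 held most of the few Acta2 counts of its line (21, 2 and 2), and without it Acta2 went from -4.41 to -6.44 and Sox6, with no count left in that line, was at least 10.2-fold lower. The ratio of Sox6 was 58.4 without EWS-OCT4 replicate 3 (exact 95% interval 10.3 to 2326), and Thy1 went from 4.81 to 5.43 without EGFP replicate 1.

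Readouts of other signalling pathways differed by pathway. Of 14 Nodal and BMP readouts, 11 rose and 2 fell (median 1.27, adjusted p = 0.0094, and adjusted p = 0.153 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 0.0031). Besides Lefty2, Lefty1 rose from 0.223 ± 0.203 to 25.5 ± 1.61 CPM and the activin subunit gene Inhbb from 1.22 ± 0.519 to 88.6 ± 10.1 CPM. The LIF-STAT3 list, which shares Klf4 and Tfcp2l1 with the pluripotency list and Gbx2 with the neural list, had 8 of 11 members higher and none lower (median 1.19, adjusted p = 0.0018, and adjusted p = 0.243 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 7.7e-05). In it Klf4 rose from 34.9 ± 1.25 to 319 ± 18.7 CPM and the LIF receptor gene Lifr from 12.5 ± 2.71 to 66.1 ± 3.33 CPM. Of 8 WNT targets, 2 rose and 2 fell (1 and 2 adjusted over the list alone), with a median of -0.25 and adjusted p = 0.627. Dkk1 had 409 counts against 1, a ratio of 319 (exact 95% interval 56.9 to 12633), Rnf43 fell from 3.56 ± 1.46 to 0.388 ± 0.145 CPM, and Cdx1 was at 1.58 ± 1.55 and 5.34 ± 0.651 CPM. The call on Cdx1 (log2 difference 1.73, adjusted p = 0.0217) was lost without EGFP replicate 1 (adjusted p = 0.0722), EGFP replicate 2 (0.0732) or EWS-OCT4 replicate 2 (0.0590), and the difference was 2.94 without EGFP replicate 3. Without that library Lefty1 had a ratio of 235 (exact 95% interval 80.3 to 1144), Lefty2 was at least 1208-fold higher, and Dkk1 had a ratio of 198 (35.0 to 7861). Without EWS-OCT4 replicate 1, Dkk1 was at least 35.1-fold lower, and without EWS-OCT4 replicate 3 its ratio was 206 (36.7 to 8152).

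Interferon response genes were lower. Of 15 tested, 13 fell, 1 rose and 1 did not pass the test (Irf1 and Stat2, named after their values were seen; median -4.86, or -4.27 with the 3 members that had no count in the EWS-OCT4 line at their bound). Irf7, Usp18 and Mx2 had no count in that line and were at least 31.9-fold, 19.3-fold and 16.8-fold lower. The antiviral gene Rsad2, chosen after its values were seen, fell from 114 ± 5.47 to 2.39 ± 0.257 CPM. The list test gave adjusted p = 3.9e-04, and adjusted p = 0.153 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 9.9e-05. With only genes of at least 10 CPM on average, the median was -1.18 (adjusted p = 0.113). Without EWS-OCT4 replicate 1, when 7 of 16 tested members had no count in that line, it was -3.10 with these at their bound. EGFP replicate 3 lay below EGFP replicates 1 and 2 over this list, with a median of -0.37 on the log2 scale.

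Metabolic and stress genes rose in part. Of 16 genes of the integrated stress response, 11 rose and 3 fell (median 1.04, adjusted p = 0.0084, and adjusted p = 0.153 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 0.0029). Chac1, a glutathione-degrading enzyme, rose from 0.183 ± 0.103 to 12.8 ± 0.590 CPM, whereas the transcription factors Atf3 and Cebpb fell from 29.7 ± 7.40 to 1.15 ± 0.451 CPM and from 85.7 ± 27.3 to 9.33 ± 5.49 CPM. Of 15 glycolysis genes, 12 rose and 2 fell (median 0.93, adjusted p = 0.0039, and adjusted p = 0.241 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 6.9e-04). Pgam1 rose from 114 ± 10.9 to 579.9 ± 136 CPM and Pdk1, which diverts pyruvate from the mitochondria, from 15.7 ± 1.74 to 50.02 ± 5.08 CPM, while the glucose transporter gene Slc2a1 fell from 1491 ± 21.8 to 363 ± 48.0 CPM. Of 18 genes of cholesterol biosynthesis, 12 rose and 2 fell (median 0.78, adjusted p = 0.0195, and adjusted p = 0.579 with an estimated correlation, the highest of 16 alternatives of this test, of which the lowest was 0.0044). That call was also lost with DESeq2 (adjusted p = 0.0821). Pmvk rose from 23.1 ± 4.996 to 102 ± 18.03 CPM and Msmo1 from 78.1 ± 21.8 to 208 ± 31.7 CPM.

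The 3 tested genes of the Y-linked list were lower in all 3 EWS-OCT4 libraries than in any EGFP library. Ddx3y fell from 112 ± 1.45 to 12.5 ± 2.81 CPM (log2 difference -3.17, SE 0.18, adjusted p = 3.1e-07), Uty fell from 16.5 ± 2.27 to 2.10 ± 0.485 CPM, and Eif2s3y fell from 28.1 ± 1.66 to 7.08 ± 0.688 CPM. The list test gave adjusted p = 0.0192, and adjusted p = 0.169 with an estimated correlation, the highest of 15 alternatives of this test, of which the lowest was 0.0036. It was 0.0723 without a filter on low counts, where the median went from -2.97 to -2.13, or -2.01 with the 2 members that had no count in 1 line at their bound. The list of mitochondrially encoded genes gave no result, since 0 of its 15 members matched a symbol in the files.

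**Figure D3:**
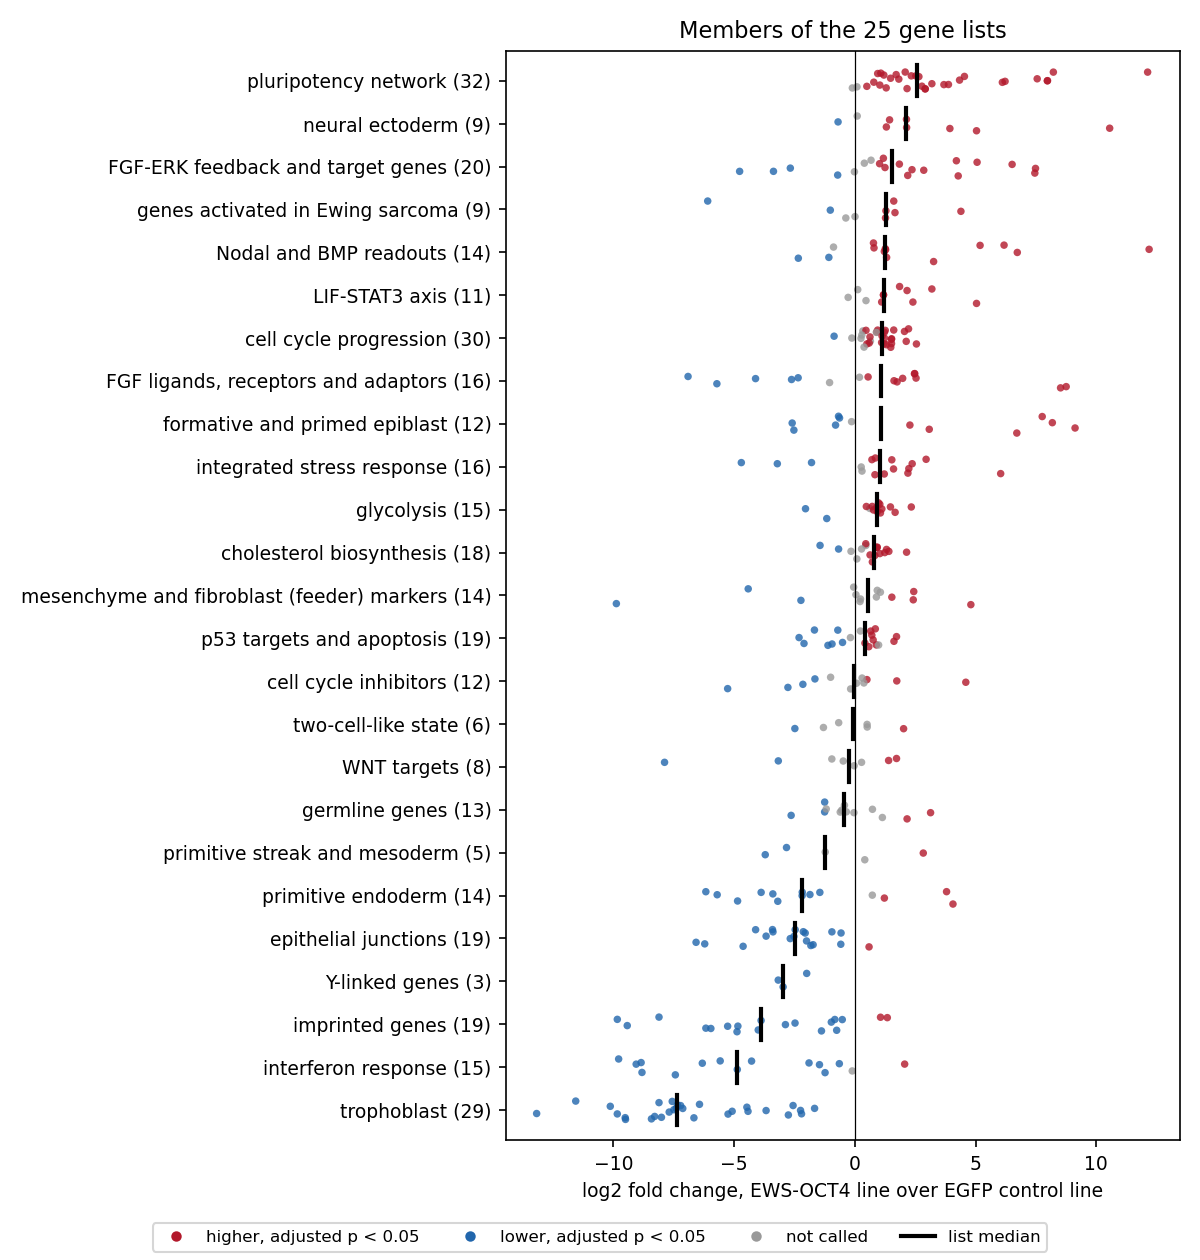
Log2 fold change of the EWS-OCT4 line over the EGFP control line (horizontal axis) for each tested member of 25 gene lists, with the number of tested members in brackets. Points are edgeR estimates from 3 libraries per line, coloured by the call at an adjusted p of 0.05, vertical position within a list carries no value, and black bars mark list medians. The medians ran from -7.34 for trophoblast genes to 2.59 for the pluripotency network, and estimates for genes with no count in 1 line depend on the fitted prior count.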

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

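A fit without Rn45s, one of the libraries numbered 1 and 2 only and one with a term for the libraries numbered 3 were chosen after seeing the data. In all, 19 alternatives were run on 130 results, not every result under each. The count of changed genes stayed within 1.5 times in each alternative that gave a count. Every shared call kept its direction in each fit compared gene by gene. Leaving out each library in turn gave 8122 to 9385 genes. Whether replicate numbers mark pairs could not be decided. Across genes, EGFP replicates 1 and 2 correlated best with EWS-OCT4 replicates 2 and 1 (0.0755 and 0.0753, own numbers 0.0402 and 0.0520). EGFP replicate 3 correlated best with EWS-OCT4 replicate 3 (0.152). These correlations are small and rest on deviations from means of 3 libraries. A replicate block gave 8968 genes, 8797 of them shared. DESeq2 gave no adjusted p for 2570 genes. With an estimated correlation all 15 list calls were lost at the same medians (pluripotency 2.59, trophoblast -7.34, FGF-ERK 1.55, cell cycle progression 1.12). That alternative estimates the correlation between genes from these samples, and why the calls were lost was not tested. The median of the FGF list changed sign, from 1.09 to -2.44, with a mean of at least 10 CPM, where 6 of 16 members were left. Medians near 0 changed sign: cell cycle inhibitors gave -0.28 to 0.11 over the left-out libraries, 0.11 with a mean of at least 10 CPM and 0.071 in libraries 1 and 2 only; the 2-cell-like list gave -1.21 to 0.82 over the left-out libraries, 0.12 with the replicate block, 0.079 with limma-voom, 0.76 in libraries 1 and 2 only and 0.088 with the term for number 3. Primitive streak went from -1.22 to 0.34 without a filter, but gave -0.65 with the 3 members at 0 in 1 line at their bound. Ewsr1 gave 0.063 in libraries 1 and 2 only. The cause of these reversals was not tested. Fry, which asks whether genes moved on balance and does not compare them with other genes, called 6 more lists (formative, streak, cell cycle inhibitors, p53, WNT and Ewing), and the Ewing list also passed with a mean of at least 10 CPM (1.34, adjusted p = 0.0380). Depth limits genes near 1 CPM, such as Pou5f1 and Fgf9.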

Other observations

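All gene families here, all single genes except Ddx3y, Uty and Eif2s3y, and all tests of the libraries numbered 3, the Y-linked genes and the extra chromosome copy, were chosen after the result was seen. Ribosomal protein genes and small nucleolar RNAs were higher in the EWS-OCT4 line. Of 80 tested cytoplasmic ribosomal protein genes, 78 rose and none fell, against 32.9% of other genes rising (median 1.24 on the log2 scale, Fisher's exact test, adjusted p = 9.9e-34). For all families here, Fisher's exact test treats the genes as independent. Genes of a family that move together would make its p-value overstate the evidence. The nucleolar genes Ncl and Npm1 rose from 2674 ± 128 to 5162 ± 592 CPM and from 851 ± 117 to 2162 ± 334 CPM. Of 38 small nucleolar RNAs, 30 rose and none fell (median 3.93, exact adjusted p = 6.5e-08). Some, such as Snora15 and Snora19 (0.0217 and 0.0433 CPM in the EGFP line), passed the filter through the EWS-OCT4 line alone. Those could not be called lower, so the p-value may overstate the evidence. By class, 25 of 27 Snora genes (median 4.79) and 5 of 11 Snord genes (median 0.96) rose, a difference by Fisher's exact test (adjusted p = 0.0053 over 3 tests). The share of Snord genes that rose did not pass a test against the 33.2% of other genes (exact adjusted p = 0.522). Snhg3, a host of such RNAs, rose from 187 ± 33.1 to 1857 ± 259 CPM. Of these RNAs, 33 lie inside a tested gene on the same strand, and 26 of the 33 had a larger log2 change than that gene, whose median was 1.05. Whether the 3′ tags at small nucleolar RNAs came from mature RNA or from other transcripts was not tested, so they may not measure mature RNA. Complex I subunits of the respiratory chain rose in 23 of 36 cases (median 0.45, exact adjusted p = 7.0e-04). Histone genes have near-identical copies. Hist2h2aa1 and Hist2h2aa2 had identical counts, as did Hist2h3c1 and Hist2h3c2. With each pair counted once 21 of 39 histone genes rose and 7 fell (median 1.13, exact adjusted p = 0.0177 for rises). Other H2A genes were nearly alike, such as Hist1h2ab (21.7 to 117 CPM) and Hist1h2ai (21.4 to 118 CPM), as shared reads could give. The p-value counts such copies as separate genes, so it may overstate the evidence. All 16 H2A genes and 4 of 5 H1 genes rose, 0 of 5 H3 and 0 of 6 H4 genes rose and 3 and 2 of them fell, and of 7 H2B genes 1 rose and 2 fell. Differences between histone classes, and which forms of histone RNA the 3′ tags came from, were not tested.

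Some other families were lower. All 8 tested prolactin family genes fell (median -6.29 with the 6 that had no count in the EWS-OCT4 line at their bound, exact adjusted p = 6.1e-04). All 7 of the Serpinb9 cluster fell too (median -8.25 with 2 at their bound, exact adjusted p = 0.0013), and both families hold near-identical copies that can share reads. EWS-OCT4 means were at most 0.0923 CPM in the prolactin family and 0.771 CPM in the Serpinb9 cluster. Both families thus passed the filter on low counts through the EGFP line alone. Their genes could not be called higher, so these p-values are no support. Of 10 annexins 8 fell (median -3.13, exact adjusted p = 0.0080), and of 8 S100 genes 7 fell (median -2.62, exact adjusted p = 0.0067). Among 10 keratins, 7 fell and 3 rose (exact adjusted p = 0.0540), with Krt17 going from 0.298 ± 0.157 to 55.5 ± 9.22 CPM and Krt42 from 0.444 ± 0.647 to 59.7 ± 10.05 CPM. Of 16 Hox genes, 9 rose and 1 fell (exact adjusted p = 0.0702 for rises). The directions held with DESeq2 size factors and without Rn45s. Other families were looked at and the families were narrowed after seeing values, so the adjustment over 20 tests does not cover every look. The metallothionein genes Mt1 and Mt2 fell from 1252 ± 55.8 to 177 ± 12.5 CPM and from 2800 ± 459 to 278 ± 34.02 CPM, and Apoe rose from 27.5 ± 4.46 to 915 ± 71.1 CPM.

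Whether another grouping of the 6 libraries would give as many changed genes was tested over all 10 splits into 3 and 3. The real split gave 9073 changed genes and each of the other 9 gave 0, so 1 split gave as many. Each of the other 9 mixes both lines in each group, so the line difference becomes spread within groups. Their counts of 0 therefore decide nothing. With 10 splits the share cannot fall low enough to exclude chance.

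The libraries numbered 3 stood apart in both lines, and EGFP replicate 3 lay nearer the EWS-OCT4 libraries. RNA or cells of the EWS-OCT4 line in EGFP replicate 3 are argued against as the whole cause. In that library 28 genes nearly silent in EGFP replicates 1 and 2 exceeded them by a median of 0.327% of their EWS-OCT4 level. The 156 genes of the pattern, selected for being higher in that library, exceeded them by a median of 16.0%. A carry-over too small to set the pattern stays open. A handling step shared by both libraries numbered 3 cannot be told apart, since their deviations correlated weakly across genes (r = 0.160), which are not independent. Trophoblast (-0.20 in the EGFP line and -0.19 in the EWS-OCT4 line), imprinted (-0.32 and -0.24) and cell cycle inhibitor medians (-0.23 and -0.31) lay below random lists in both, but the cell cycle progression list moved apart (0.41 and -0.11). A less advanced response to OCT-4 loss in EGFP replicate 3 stays open. Its pluripotency median of 0.42 and trophoblast median of -0.20 against replicates 1 and 2 restate that it lay nearer the EWS-OCT4 line and decide nothing. Of 10 other lists outside the range of random lists, 6 had the sign of their median between the lines (such as cholesterol, 0.48). The other 4 had the opposite sign (2-cell-like 1.38, germline 0.45, LIF-STAT3 -0.28 and mesenchyme -0.27). This tally decides nothing either, since the medians between the lines include EGFP replicate 3. The 2-cell-like median between the lines was -0.08 with that library and 0.82 without it.

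The Y-linked genes Ddx3y, Uty and Eif2s3y were lower in the EWS-OCT4 line, while Uba1y, the other tested gene of chromosome Y, was near the floor at 1.45 ± 0.328 and 1.13 ± 0.280 CPM and did not pass the test (-0.36, SE 0.45). Loss of the Y chromosome from a share of cells is argued against as the whole cause, since the largest and smallest falls differed by 1.18 on the log2 scale (SE 0.26). Reads of X-linked partners as the only source of the counts at Y-linked genes are argued against. The ratio to the partner fell for all 3 genes, least for Uty over Kdm6a (-0.83, SE 0.32). A part of the counts could still come from partner reads. The partners Ddx3x and Kdm6a fell too, by 1.22 and 2.14 on the log2 scale, while Eif2s3x did not pass the test (-0.12, adjusted p = 0.656). Loss from some cells together with regulation, or with partner reads in part of the counts, could account for the pattern and was not tested.

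Genes on chromosomes 8 and 19 were higher as a body in the EWS-OCT4 line. The median shift from all genes was 0.51 over 700 genes of chromosome 8 (bootstrap 95% interval 0.43 to 0.60) and 0.48 over 448 genes of chromosome 19 (0.28 to 0.60). Each had adjusted p = 0.0010 against 10000 random gene sets, from the smallest p that so many sets can give. These sets and the bootstrap treat genes as independent and do not measure the spread between libraries. Transcript GC is argued against, since the smaller shift was 0.46 after its trend was removed, and so is a cluster in 1 part, since all 5 parts of each chromosome lay above 0, the lowest at 0.26. An extra copy of each chromosome, which in every cell would give 0.58, may account for it, as the larger shift was 0.51, but this is a hypothesis from the same data. Smaller shifts also passed for chromosome 12 (-0.33, 2 of 5 parts above 0), chromosome 16 (-0.22, 0 of 5 parts above 0) and chromosome 1 (0.16, 3 of 5 parts above 0). Their adjusted p against random gene sets was 0.0013, 0.0228 and 0.0228.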
